A study of Mus musculus with 12 samples.

How the data were processed

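RNA from lung tissue of A/J mice was labelled with biotin after Trizol extraction, per the labels' protocols, and hybridised to Affymetrix MG_U74Av2 arrays, 1 array for each of 12 samples. The authors deposited 1 table of linear intensity values, the MAS5 signal of each probe set, per the submitters' processing notes; the version of MAS5, the scaling target and the genome build are not given in the sources used here. Intensity values of the deposited table had a 2% trimmed mean (2% from each end) that differed by 0.00897% at most between arrays, so they had been scaled to a shared level before deposit and were not scaled again. Such scaling hides any change that moves most transcripts one way. MAS5 subtracts mismatch signals, which makes low values noisy. Detection calls were not used here, and probe-level intensities were not analysed here.

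The table held 12488 probe sets, and all 12 columns matched a sample. After removal of 66 control probe sets, 12422 remained, of which 10833 had 1 gene symbol, 396 had several and 1193 were not listed in the platform annotation and are unnamed here. Symbols were checked through the Entrez gene number against a table of RefSeq genes (assembly GRCm38.p6), where 10817 of the 10833 matched and 0 needed updating. Values were log2-transformed with no pseudocount; 0 values were at or below 0. Probe sets with a mean log2 value under the 40th percentile of all probe sets, a signal of about 108, were left out, which left 7453. For gene lists and named genes the probe set with the highest mean stood for its gene, which gave 5731 genes, 893 of them with more than 1 tested probe set.

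The 2 time points were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust, with statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and 5% false discovery. Adjusted p of single genes throughout are from this fit. Differences are log2 values at 42 weeks minus 24 to 26 weeks. The design, the gene lists, the rule for named genes and the alternatives were written before the data were examined, except where the text says otherwise. In the rule, up to 12 genes per direction are named among those past the test with the same sign against the AJ and the LZ arrays at 24 to 26 weeks, all of them where fewer pass; of a list, up to 4 members past the test or, where none passed, up to 2 with the smallest p, with values only; and sex-linked genes and lung reference genes always. Of these, Sftpa1 and Sftpd have no value here. Of 50 lists, 47 had at least 3 measured members and were tested with camera (preset correlation 0.01, and again with an estimated correlation), with adjustment over the 47. List medians per array are medians of log2 values relative to each gene's median over the 12 arrays.

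The title prefix and number range of the samples, which the labels do not explain, were compared within each time point in 1 fit of all 12 arrays with the 4 number ranges as groups. The run records gave a hybridisation and scan day for each array, and these 4 days held the same arrays as the 4 number ranges. As each day held 1 time point, run day was fitted as a random block with duplicateCorrelation (consensus correlation 0.227). The labels give each sample its own title without stating that each came from its own animal, so p-values measure the spread between these samples.

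The alternatives were quantile normalization, arrays set to equal medians, no filter or a 60th percentile filter on dim probe sets, a pseudocount at the 20th percentile of all values (28.7), eBayes without trend and robust, array weights, the title prefix or run day as a block, subsets of arrays, each array left out in turn, stricter thresholds and an exact permutation test. The fit was tested on simulated data with the real means and spreads of the 7453 probe sets in the comparison of time points, in 20 data sets with 200 changed probe sets each. It recovered 51.9% of changes of 1.5-fold, 86.4% of those of 2-fold and 98.6% of those of 4-fold, with 4.05% of calls false. The simulation had no run day effects. Camera called the list that was shifted by 0.5 (log2) in all 20 simulated data sets and made 2 other calls in all. Genes were drawn independently there, so this does not test camera where list members vary together. The shifted list, oxidative phosphorylation, had a median log2 difference of 0.14 in the real arrays. The median standard error of a log2 difference was 0.15.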

Results

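Messenger RNA levels were measured in lung tissue of A/J mice, an inbred strain prone to lung tumours, with one Affymetrix mouse array (MG_U74Av2) for each of 12 samples. All samples were controls that had received saline, and per the labels 5 were taken 24 to 26 weeks and 7 were taken 42 weeks after the injection. The earlier samples were titled AJ1, AJ2, AJ4, LZ2 and LZ3, and the later ones LZ22 to LZ25 and LZ61 to LZ63. The run records placed the arrays on 4 run days, each with samples of 1 time point only: AJ1, AJ2 and AJ4 on day 1, LZ2 and LZ3 on day 2, LZ22 to LZ25 on day 3 and LZ61 to LZ63 on day 4. The 2% trimmed mean signal was 500.3 on every array to within 0.00897%, and the number of arrays limits the precision. Spearman's rho between arrays, across 7453 probe sets, had a median of 0.958 for the 13 pairs of the same run day, 0.945 for the 18 pairs of the same time point on other days and 0.941 for the 35 pairs of different time points. No pair of arrays held the same values, the highest rho being 0.979.

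The first question was which transcripts differ in the lung of these saline-injected controls between the 2 time points. Cyp1a1, the cytochrome P450 that the aryl hydrocarbon receptor induces, fell 4.57-fold, from a signal of 559 ± 208 (SD, n = 5) at 24 to 26 weeks to 116 ± 20.7 (SD, n = 7) at 42 weeks. The log2 difference was -2.19 with a standard error of 0.23 and a 95% interval of -2.68 to -1.71 (limma, adjusted p = 0.00044). The readings at 42 weeks, from 81.6 to 148.7, lie around the level of 108 under which probe sets were left out, and detection calls were not used, so these readings are not shown to lie above background. The log2 difference was -1.95 with a pseudocount, so the size of the fall is uncertain. Another Cyp1a1 probe set, too dim to be tested, had a mean of 35.8 at 24 to 26 weeks and 29.4 at 42 weeks. Its readings ran from 10.2 to 68.1 over all arrays, under the level of 108, so it cannot decide whether the fall holds. The fall of Cyp1a1 thus rests on the tested probe set alone. Jkamp, a protein of the endoplasmic reticulum membrane that binds the kinase JNK1, fell 3.22-fold, from 801 ± 293 to 239 ± 52.6. Tmed9, a cargo receptor of the early secretory pathway, fell 1.87-fold, from 1348 ± 324 to 711 ± 85.3, and Rrp1b, a nucleolar protein, fell 1.81-fold, from 296 ± 28.6 to 165 ± 20.4. Agap3, a GTPase-activating protein for Arf, rose 1.60-fold, from 526 ± 56.6 to 845 ± 115. Their limma adjusted p was 0.011 for Jkamp, 0.014 for Tmed9, 0.012 for Rrp1b and 0.028 for Agap3, and for all 5 genes each array at 42 weeks lay beyond every array at 24 to 26 weeks. The sixth probe set past 5% false discovery was the dimmer of the Cavin1 probe sets. Cavin1 is a coat protein of caveolae, and this probe set rose from 762 ± 106 to 1251 ± 96.7 (log2 difference 0.72, adjusted p = 0.011). It was named after its values were seen, because the brighter Cavin1 probe set, which stands for the gene here, read 2870 ± 377 and 3003 ± 380 (log2 difference 0.07, adjusted p = 0.83).

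**Figure D1:**
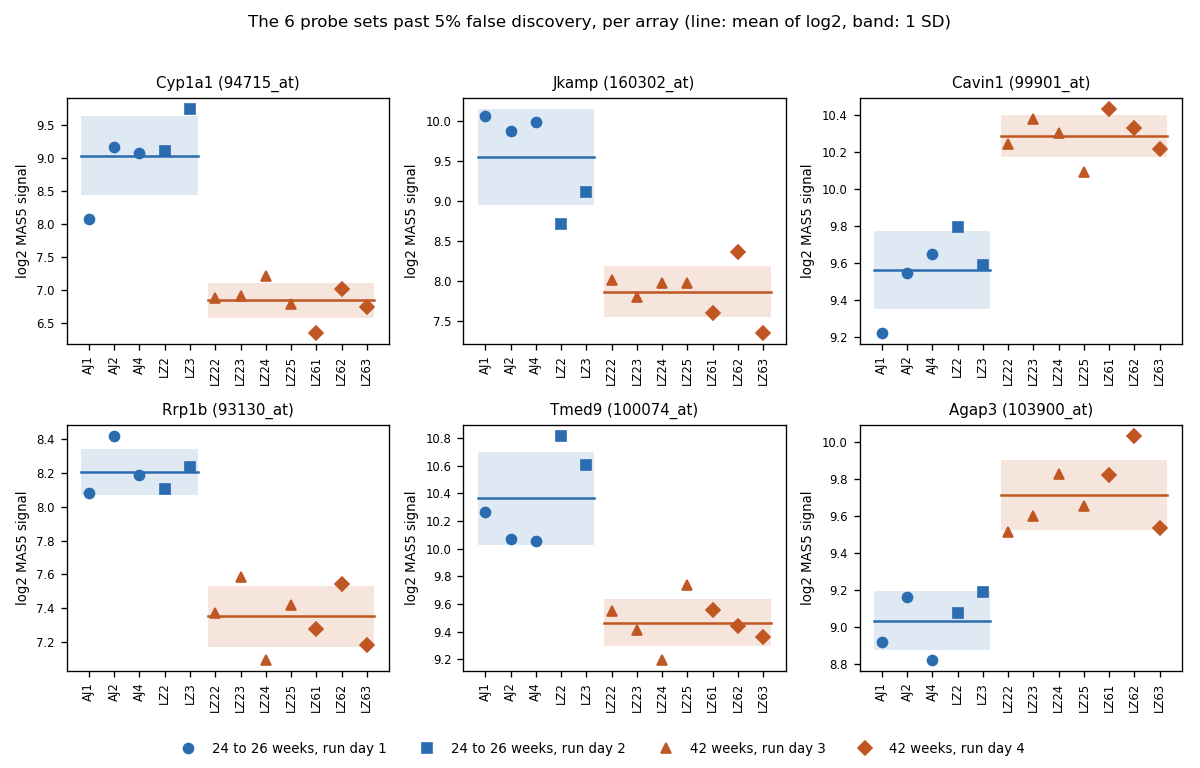
Log2 signal of the 6 probe sets past 5% false discovery on each of the 12 arrays, with colour for the time point, symbol for the run day, a line for the group mean and a band of 1 SD. In each panel the 2 time points do not overlap, and Cyp1a1 lies at a mean signal of 559 in the earlier and 116 in the later group.

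In all, 6 of 7453 probe sets passed 5% false discovery, 2 of them higher and 4 lower at 42 weeks, and 1097 had an unadjusted p under 0.05. An exact permutation test per probe set called 0, with 1031 at an unadjusted p under 0.05. Each of the 6 probe sets had its smallest possible p of 0.00126 there, which gave an adjusted p of 0.162. With 792 splits, single probe sets cannot reach an adjusted p under 0.05 in this exact test, however far apart their groups lie. Its count of 0 is thus no evidence against the 6. The groups did not overlap in 112 probe sets, or 1.5%. Chance would give 0.253% if all arrays were exchangeable, which does not take into account that arrays of a run day resemble each other. With run day as a random block 1 probe set, Cyp1a1, passed (adjusted p = 0.00704; from 1.0e-05 to 0.0422 over the 26 alternative limma fits that kept Cyp1a1), while Jkamp (0.074), Tmed9 (0.12), Cavin1 (0.13), Rrp1b (0.17) and Agap3 (0.29) had larger adjusted p. All arrays at 42 weeks are LZ-titled. With the title prefix as a block, the difference is thus 42 weeks against LZ2 and LZ3 alone, the same as with LZ arrays only. With this block, Cyp1a1 (log2 difference -2.58) and Tmed9 (-1.25) each had a limma adjusted p of 0.0014. The other 4 probe sets did not pass, with a log2 difference of -0.82 for Rrp1b, 0.59 for Cavin1, 0.58 for Agap3 and -1.05 for Jkamp. Jkamp itself was higher on the AJ than on the LZ arrays at 24 to 26 weeks (log2 difference 1.06, adjusted p = 0.040). No run day held both time points, so no value within a day can be given. Leaving out the 3 arrays whose muscle, fat or squamous markers stood apart (described further on; an alternative chosen after seeing the data) left 1 call, Cyp1a1, with an adjusted p of 0.0163. Agap3 lost its call without any 1 of AJ1, AJ2, AJ4, LZ24, LZ25 and LZ61 (adjusted p from 0.057 to 0.142) and Rrp1b lost it without AJ2 (0.061). The count of calls moved to 38 without LZ2, 30 without LZ3, 16 without LZ62 and 15 without LZ63.

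Xenobiotic metabolism, the list to which Cyp1a1 belongs, had 41 measured members, of which 0 rose, 1 fell and 40 did not pass. The count of falls was also 1 when adjusted over the list alone. This was the only one of the 47 tested lists with a member past the test over all probe sets. Among the lung reference genes, which did not pass, surfactant protein C (Sftpc) read 25777 ± 9348 at 24 to 26 weeks and 33697 ± 4352 at 42 weeks (log2 difference 0.45, adjusted p = 0.27). Sftpb read 13198 ± 1929 and 16375 ± 2857 (0.30, adjusted p = 0.34), and the club cell secretoglobin Scgb1a1 read 22201 ± 7371 and 28208 ± 3405 (0.40, adjusted p = 0.28). With the title prefix as a block the difference of Sftpc was -0.06 and that of Scgb1a1 was -0.07. Over all alternatives the difference ran from 0.015 to 0.44 for Sftpb, from -0.065 to 0.79 for Sftpc and from -0.069 to 0.70 for Scgb1a1. As a check of the arrays, the Y-linked Eif2s3y read between 285 and 637 on the 12 arrays (477 ± 108 and 348 ± 57.2, adjusted p = 0.22), and the X-inactivation transcript Xist, too dim to be tested, between 4 and 193. The array design marks the Eif2s3y probe set as shared by related sequences. The Y-linked Kdm5d (6.9 to 41.9), Uty (59.3 to 138.9) and Sry (4.7 to 25.7, and 12.4 to 73.1 on another probe set) were too dim to be tested. These readings alone do not give the sex of the samples.

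The lists of immunoglobulins and plasma cells, MHC class II, complement and acute phase, oxidative phosphorylation and ribosomal proteins, 5 of 47, were shifted upward at 42 weeks relative to other genes in camera's test with a preset correlation, and 0 downward. With an estimated correlation 0 of 47 lists passed, and all 5 had an adjusted p = 0.90. Transcripts of immunoglobulins and plasma cells, the products of antibody-secreting cells, had a median log2 difference of 0.79 over 28 measured genes (adjusted p = 1.5e-06, and adjusted p = 0.90 with an estimated correlation). Its call was lost with LZ61 to LZ63 only at 42 weeks, where the median was 0.25, and the mean of its array medians was -0.26, -0.31, 0.60 and -0.18 on run days 1 to 4. Of the immunoglobulin list 0 genes rose, 0 fell and 28 did not pass singly, 23 having a positive difference, and 16 rest on probe sets that the array design marks as shared by related sequences, so single family members are uncertain. The heavy chain gene Igha read 4221 ± 1964 and 7642 ± 2158 (log2 difference 0.96, adjusted p = 0.26). The difference of Igha was 0.62 without LZ2, 0.47 against the AJ arrays and 1.71 against the LZ arrays at 24 to 26 weeks. The light chain gene Igkv6-23 read 11216 ± 2664 and 17708 ± 5118 (0.63, adjusted p = 0.22). MHC class II genes, which present antigen to helper T cells, had a median of 0.16 over 11 genes, 0 past the test (adjusted p of the list = 0.038, and adjusted p = 0.90 with an estimated correlation). The median was 0.098 without LZ23, 0.33 without LZ63 and -0.018 with LZ61 to LZ63 only at 42 weeks. H2-Aa read 6905 ± 310 and 9568 ± 1689 (adjusted p = 0.14) and was 1 member higher when adjusted over the list alone. H2-Eb1 read 4086 ± 670 and 5275 ± 1134 (adjusted p = 0.36). Complement and acute phase genes had a median of 0.21 over 13 genes, 0 past the test (adjusted p of the list = 0.038, and adjusted p = 0.90 with an estimated correlation). C1qc was at 1129 ± 184 and 1677 ± 394 (adjusted p = 0.18) and C1qa at 1315 ± 252 and 1786 ± 440 (adjusted p = 0.28).

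Oxidative phosphorylation genes had a median log2 difference of 0.14 over 57 genes, 0 past the test and 1 higher when adjusted over the list alone (adjusted p of the list = 2.2e-05, and adjusted p = 0.90 with an estimated correlation). The median was 0.071 without LZ63, and the call was lost with LZ22 to LZ25 only at 42 weeks, where the median was 0.030. The complex I subunit Ndufa7 read 5033 ± 610 and 7006 ± 775 (adjusted p = 0.064), and another, Ndufb3, read 1621 ± 398 and 979 ± 238 (adjusted p = 0.12), the opposite direction. The array median of the oxidative phosphorylation list was 0.53 on LZ63, an array with high skeletal muscle markers, and between -0.07 and 0.13 on the other arrays at 42 weeks. Ribosomal protein genes had a median of 0.16 over 25 genes (-0.01 after quantile normalization), 0 past the test (adjusted p of the list = 8.5e-05, and adjusted p = 0.90 with an estimated correlation). Rpl19 was at 10614 ± 1803 and 13736 ± 2198 (adjusted p = 0.22) and Rps28 at 15372 ± 4613 and 20128 ± 2117 (adjusted p = 0.23). The ribosomal list had an adjusted p of 0.71 after quantile normalization, and a median of 0.0014 with the title prefix as a block (adjusted p = 0.82). An exact two-sided permutation test of the array medians of each list takes arrays and not genes as the units. This exact test gave p = 0.12 for immunoglobulins, 0.24 for MHC class II, 0.086 for complement, 0.29 for oxidative phosphorylation and 0.047 for ribosomal proteins. Adjusted over the 47 lists these 5 values lay from 0.73 to 0.90. The smallest exact p of the 47 lists, 0.0038 (0.18 adjusted), belonged to thymus and lymph node markers, named here because of this value. That list did not pass camera's test (8 genes, median 0.50, adjusted p = 0.12), and its median was 0.17 with the title prefix as a block. Complement lost its call with the prefix block (adjusted p = 0.50), with LZ22 to LZ25 only or LZ61 to LZ63 only at 42 weeks, and without any 1 of AJ2, AJ4, LZ3, LZ23, LZ24 and LZ61. MHC class II lost it with LZ61 to LZ63 only, with AJ arrays only at 24 to 26 weeks and without any 1 of AJ4, LZ2, LZ3, LZ22, LZ23, LZ24 and LZ61, and its array median was -0.67 on LZ63. Both lists also lost it after quantile normalization, with the medians of the arrays set equal and without the filter on dim probe sets. The count of 5 lists moved to 3 without AJ4, LZ23 or LZ24, 9 without AJ1 and 10 without LZ63.

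**Figure D2:**
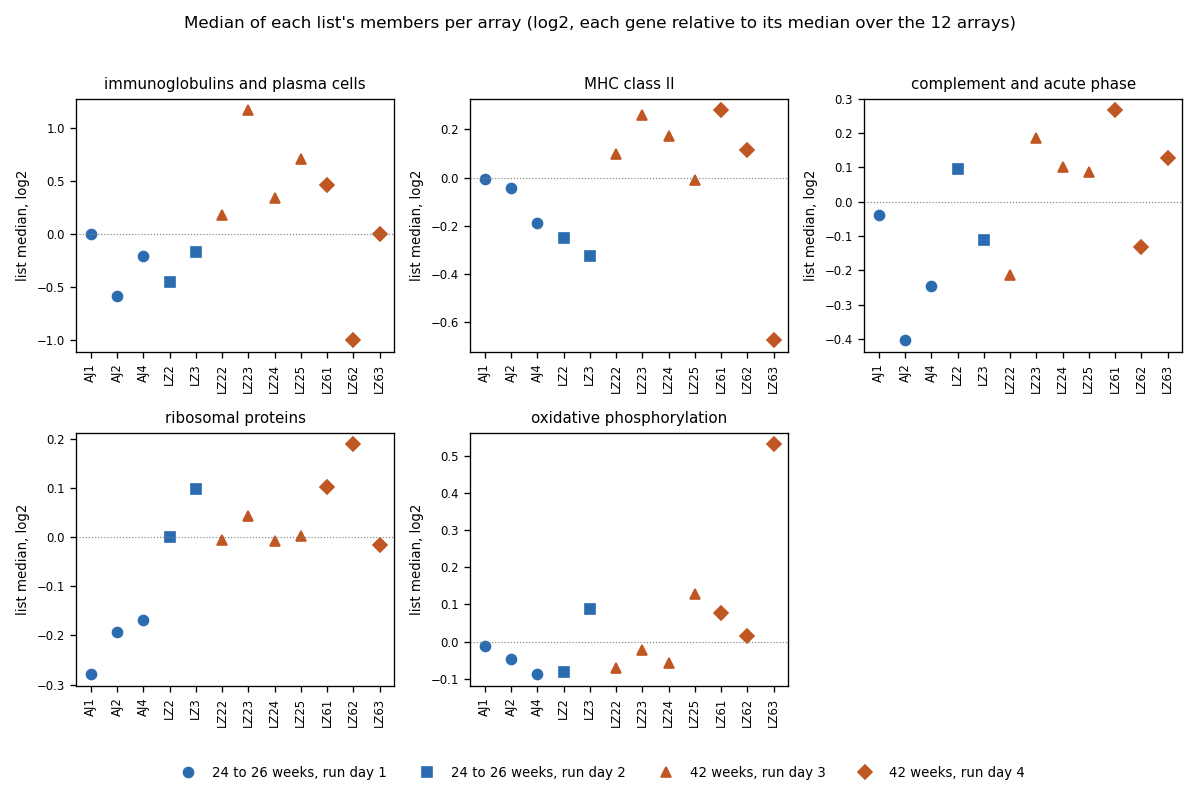
Median of the members of the 5 lists past camera's preset test on each array, in log2 units relative to each gene's median over the 12 arrays, with colour for the time point and symbol for the run day. Immunoglobulins were highest on LZ23, at 1.17, and below 0 on LZ62 and LZ63 within the 42 week group, and oxidative phosphorylation was at 0.53 on LZ63.

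The other 42 lists did not pass (adjusted p from 0.051 to 0.99, medians from -0.53 to 0.50), and in 8 of the 47 lists the median, mean and test differed in sign. Alveolar type 2 cell markers lay closest to the threshold (16 genes, median 0.15, adjusted p = 0.051) and passed in 12 of 29 alternatives, among them without any 1 of LZ2, LZ3 (median 0.23), LZ25 and LZ63. Against LZ2 and LZ3 alone the median was -0.017. That is the difference both with the title prefix as a block (adjusted p = 0.94) and with LZ arrays only (adjusted p = 0.95). B cell markers had a median of 0.22 over 13 genes (adjusted p = 0.11). The median was 0.060 without LZ61 and 0.35 without LZ63, and the list passed without any 1 of AJ1, LZ62 and LZ63. Blnk was at 264 ± 33.0 and 357 ± 115 and Cd79a at 783 ± 93.7 and 1119 ± 576. The log2 difference of Blnk was 0.39 (0.26 without LZ24 and 0.48 without LZ22) and that of Cd79a 0.38 (0.19 without LZ61 and 0.54 without LZ63). T cell markers had a median of 0.07 over 13 genes (-0.015 without LZ24 and 0.16 without LZ63, adjusted p = 0.29), 2 of them higher when adjusted over the list alone, with Thy1 at 239 ± 45.0 and 354 ± 70.5 and Cd3g at 92.5 ± 29.4 and 176 ± 62.5. Markers of fibroblasts and other mesenchyme had a median of -0.17 over 17 genes (-0.082 without LZ2, adjusted p = 0.27), 2 of them lower when adjusted over the list alone, with the microfibril protein gene Mfap4 at 4683 ± 885 and 2802 ± 586 and the growth factor gene Fgf7 at 262 ± 26.2 and 162 ± 45.0. Circadian clock genes, a list that passed without AJ1, had a median of -0.19 over 15 genes (adjusted p = 0.22), 1 lower when adjusted over the list alone, with the clock output gene Dbp at 526 ± 154 and 286 ± 70.9 and Nr1d2 at 902 ± 199 and 641 ± 143. The hour of sampling is not given in the sources used here. Single-gene adjusted p over all probe sets were from 0.064 to 0.55 for these 8 genes.

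Markers of tissues beside the lung varied between arrays within the 42 week group. Myh6, the atrial myosin heavy chain, read 6.6 on LZ22 and 45.3 on LZ24, against 732 to 1678 on the arrays at 24 to 26 weeks, and the cardiac muscle list had array medians of -4.03 and -3.79 there. The same list had a median difference between the time points of -0.53 over 17 genes (-1.15 without LZ63 and -0.020 without LZ24, adjusted p = 0.94). On LZ63 the skeletal actin gene Acta1 read 20112 and the squamous keratin gene Krt4 read 19799, against at most 372 and 322 at 24 to 26 weeks. Myh6, Acta1 and Krt4 were named after their values were seen. The array median on LZ63 was 4.53 for skeletal muscle, 1.97 for cardiac muscle, 1.95 for adipose tissue and 0.50 for cartilage and squamous epithelium. Between the time points, with all arrays, these lists did not pass camera's test. Skeletal muscle had 8 genes and a median of 0.24 (-0.57 without LZ63 and 0.55 without LZ22, adjusted p = 0.49). Adipose tissue had 8 genes and 0.16 (0.0011 without LZ63 and 0.33 without LZ24, adjusted p = 0.33). Cartilage and squamous epithelium had 9 genes and 0.10 (0.020 without LZ63 and 0.17 without AJ4, adjusted p = 0.48). The cardiac list passed with LZ22 to LZ25 only at 42 weeks (median -1.69), with LZ61 to LZ63 only (0.67) and without LZ22, LZ24 and LZ63 (0.30), and skeletal muscle (1.47) and adipose tissue (0.98) passed with LZ61 to LZ63 only. The first principal component held 26.2% of the variance and set LZ63 at 44.8, with the other arrays between -18.3 and 10.4.

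**Figure D3:**
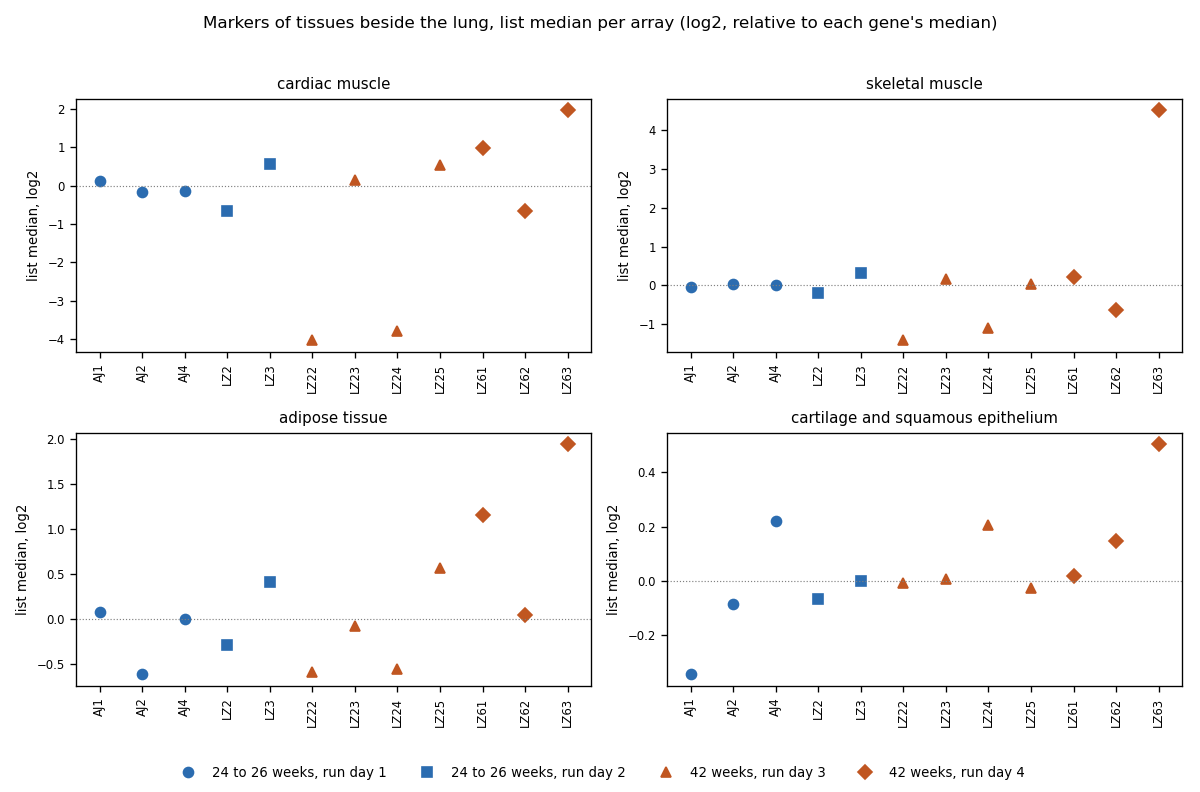
Array medians of 4 lists of markers of tissues beside the lung, in log2 units relative to each gene's median over the 12 arrays, with colour for the time point and symbol for the run day. Cardiac muscle markers were at -4.03 on LZ22 and -3.79 on LZ24, and skeletal muscle markers at 4.53 on LZ63.

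The second comparison asked whether the AJ-titled and LZ-titled arrays of the same time point, run on days 1 and 2, differed. Igtp and Gbp7, which encode GTPases induced by interferon, were higher on the AJ arrays. Igtp read 1570 ± 67.1 (SD, n = 3) against 366 ± 102 (SD, n = 2) (log2 difference 2.13, limma adjusted p = 0.0099), and Gbp7 read 3199 ± 701 against 743 ± 46.2 (2.08, adjusted p = 0.038). The phosphatase gene Dusp8 was also higher (556 ± 138 against 162 ± 67.0, adjusted p = 0.035). The cyclin gene Ccnd2 (121 ± 21.4 against 415 ± 69.6, adjusted p = 0.0043), the Argonaute gene Ago2 (303 ± 46.6 against 805 ± 215, adjusted p = 0.0082) and the matrix gene Tnxb (424 ± 100 against 1007 ± 217, adjusted p = 0.016) were lower. In all, 186 probe sets passed, 84 higher and 102 lower on the AJ arrays. Of 25 interferon response genes 4 were higher, 0 lower and 21 did not pass (median 0.44, camera adjusted p = 0.00025). Of 25 ribosomal protein genes 0 were higher, 6 lower and 19 did not pass (median -0.20, adjusted p = 2.1e-05). MHC class I and peptide loading (median 0.33, adjusted p = 0.0043) was also shifted upward on the AJ arrays. Immediate early genes (-0.21, adjusted p = 0.0011) and alveolar type 2 cell markers (-0.20, adjusted p = 0.017) were shifted downward. All these lists had a camera adjusted p = 0.96 with an estimated correlation. The AJ arrays also had a lower 99th percentile of signal (7427 to 7768, against 8862 on LZ2 and 9205 on LZ3) and a higher ratio of the 3' to the 5' probe set of beta-actin (1.24 to 1.28, against 1.06 and 1.05), while the same ratio of Gapdh was 0.767 to 0.805, against 0.883 on LZ2 and 0.766 on LZ3. The interferon list had a median of -0.15 between the time points (-0.079 without AJ2 and -0.25 without LZ24, adjusted p = 0.67), with Ifitm3 at 6485 ± 525 and 5475 ± 727 and Ifi204 at 1301 ± 318 and 915 ± 339, and its median was 0.17 with the title prefix as a block (adjusted p = 0.0082). The count rested on few arrays: it was 54 without AJ2, 19 without AJ4, 35 without LZ2, 0 without LZ3 and 374 without LZ63, whose spread enters the shared fit.

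The third comparison asked whether the arrays of the 2 number ranges at 42 weeks, run on days 4 and 3, differed. The genes Peg3 (173 ± 3.26, SD, n = 3, against 78.3 ± 31.0, SD, n = 4, limma adjusted p = 0.048), Zbtb20 (459 ± 29.9 against 203 ± 63.6, adjusted p = 0.037) and Tnxb (735 ± 143 against 333 ± 49.7, adjusted p = 0.029) were higher on LZ61 to LZ63. The small GTPase gene Rab20 (65.7 ± 12.6 against 260 ± 59.0, adjusted p = 0.037), the kinase gene Mapk7 (67.4 ± 40.9 against 214 ± 52.4, adjusted p = 0.035) and the nucleoporin gene Nup54 (191 ± 99.9 against 415 ± 78.6, adjusted p = 0.045) were lower. Of 18 alternatives, Peg3 passed in 2, Zbtb20 and Nup54 in 4 each and Rab20 and Mapk7 in 5 each, while Tnxb passed in 14 of 19. In all, 112 probe sets passed, 31 higher and 81 lower, and 8 of them were also among the 186 of the second comparison. Immunoglobulin transcripts were shifted downward on LZ61 to LZ63 relative to LZ22 to LZ25 (median -0.85 over 28 genes, 0 past the test singly, camera adjusted p = 0.00085), and oxidative phosphorylation (median 0.25, adjusted p = 8.1e-07) and cardiac muscle (median 2.36, adjusted p = 2.4e-06) upward. Also past the preset test, with camera adjusted p from 0.0018 to 0.046, were skeletal muscle (median 2.56), adipose tissue (1.19), smooth muscle and pericytes (0.34) and collagens and extracellular matrix (0.093) upward. Alveolar macrophages (-0.44), monocytes and other macrophages (-0.36), cell cycle (-0.19) and proteasome (-0.11) were past it downward. All these lists had a camera adjusted p = 0.76 with an estimated correlation. The cardiac array medians were -4.03 on LZ22 and -3.79 on LZ24, against 0.15 on LZ23, 0.53 on LZ25 and -0.67 on LZ62, and oxidative phosphorylation was at 0.53 on LZ63. The 3' control probe set for 18S ribosomal RNA read 21883 on LZ61, 2052 on LZ62 and 8024 on LZ63, against 150.4 to 314.2 on LZ22 to LZ25. The genes and lists named in both comparisons of run days were chosen after their values were seen. Leaving out any single array moved the count of 112 to between 0 and 84: it was 0 without AJ2, LZ22, LZ23 or LZ25, 55 without AJ1, 27 without AJ4, 26 without LZ2, 32 without LZ3, 35 without LZ24 and 34 without LZ63. Setting the medians of the arrays equal gave 33 higher and 259 lower in this comparison and 58 higher and 198 lower in the second.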

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

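The tests on LZ63, the fit without LZ22, LZ24 and LZ63, the exact tests of array medians and the estimated correlation with the title prefix as a block were chosen after the results were seen, and the planned fits with a block and the subsets of arrays were taken as tests of an explanation only then.

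A sample lay far from the others of its group in 12 of 102 groups of values checked, where chance marks about 5%. At 42 weeks LZ63 was the distant array for Pvalb (4310 against at most 999.5 on the others), Mylpf (894 against at most 167), Lor (12579 against at most 435), H2-Eb1 (2959 against at least 5033) and Sftpb (10600 against at least 15800). It was also the distant array for the array medians of skeletal muscle (4.53), oxidative phosphorylation (0.53), MHC class II (-0.67) and alveolar type 2 cells (-0.28). LZ61 was distant for Dbp (155.6 against at least 259.9), and at 24 to 26 weeks LZ2 was distant for Blnk (208.7 against at least 268.5) and Ndufa7 (6108 against at most 4875).

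The muscle and squamous transcripts on LZ63 form the first pattern. All 8 measured skeletal muscle genes (100%), which also passed the filter on dim probe sets, were over 4-fold above the median array on LZ63. Acta1 read 20112 and Krt4 read 19799 there. Of the squamous genes checked (Krt4, Krt13, Lor, Sprr1a and Krt5), only Krt4 and Lor were measured, and both were over 4-fold above the median array. Sprr1b, another measured squamous gene, was outside this check, and LZ63 was not the distant array for it. A sample of another tissue under a wrong label would lack surfactant transcripts, yet Sftpc on LZ63 was 1.59 times the lowest of the other arrays. A change of lung with the time point would be seen on other arrays at 42 weeks, but 0 of these 6 had a skeletal muscle median above every array at 24 to 26 weeks. A candidate explanation that stays open is that striated muscle and squamous epithelium, tissues that meet in the mouse oesophagus, were carried along with the lung of this sample.

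The lower Cyp1a1 at 42 weeks is the second pattern. Shifts between run days were tested with run day as a random block, where Cyp1a1 had a limma adjusted p of 0.00704. That fit uses 1 correlation (0.227) for all probe sets, so it cannot exclude a shift between days particular to a gene. Within a time point, differences between days among genes past the test reached 2.13 for Igtp and -1.98 for Rab20 (log2). Day 4 minus day 3 had larger list medians, 2.56 for skeletal muscle and 2.36 for cardiac muscle, with 0 members past the test. Cyp1a1 itself differed by -0.65 between days 1 and 2 and by -0.25 between days 4 and 3. Markers of tissues beside the lung were low on LZ22 and LZ24 (cardiac list medians of -4.03 and -3.79) and high on LZ63 (skeletal muscle 4.53). These departures as the source of the fall are argued against by the limma adjusted p of 0.0163 without these arrays. Lower activity of the aryl hydrocarbon receptor was tested on its other targets, of which only 3 of 10 listed genes were measured. Their median log2 difference was 0.031, above the bound of -0.5 set beforehand (exact permutation p = 0.97). The single differences were 0.031 for Tiparp (standard error 0.30), 0.12 for Aldh3a1 (0.57) and -0.21 for Cyp1b1 (0.21). With standard errors of this size the 3 genes did not fall with Cyp1a1 as a set, but they cannot exclude lower activity. Something shared by both later run days cannot be told apart from the time point, since 0 of the 4 run days held both. A technical difference of that kind is present: the BioDn 3' control, a bacterial transcript added in a fixed amount, read 7467.8 to 13039.5 at 24 to 26 weeks. It read 2197.9 to 4368.4 at 42 weeks. Age or time after saline also stays open as an untested biological explanation.

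The higher immunoglobulin transcripts at 42 weeks are the third pattern. A difference between AJ-titled and LZ-titled arrays was not excluded beyond the spread between arrays: with the title prefix as a block the median was 0.90 against 0.79 without it (preset adjusted p = 3.0e-07), and AJ and LZ arrays at 24 to 26 weeks had means of -0.26 and -0.31, but the difference of array medians among LZ arrays alone, 0.58, had an exact permutation p of 0.28 over 36 splits. An adjusted p of 0.96 with an estimated correlation and this block, against 0.90 without it, is no evidence for such a difference either. The spread between arrays of 1 group of transcripts that vary together stays open: the array medians were 0.27 ± 0.68 (SD, n = 7) and -0.28 ± 0.23 (SD, n = 5), with an exact permutation p of 0.12, and the call was lost with LZ61 to LZ63 only at 42 weeks (median 0.25 against 0.79). A rise with age may be present but was not separated from this spread.

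Of 100 splits of the 12 arrays into 5 and 7, 1, the real one, gave as many as 6 probe sets and the highest other gave 1, which argues against a random grouping of single arrays as the source of the count. The other drawn splits do not keep run days whole. Only 2 splits into 5 and 7 do: the real one gave 6 probe sets, with 1097 at an unadjusted p under 0.05, and days 2 and 4 against days 1 and 3 gave 3, with 926. They are too few for a share under 0.05, so chance in how run days fell into the time points was not excluded. For gene lists, 83 of the 100 splits gave at least the real 5 lists and the highest other gave 22, so chance cannot be excluded. The median of the other splits was 10 lists, above the real 5. The preset test's count of lists is thus no evidence of a difference between the time points. With an estimated correlation 0 lists passed, which goes with list members that vary together beyond the preset correlation. That result does not tell this apart from a structure among the samples, which stays open. For the 2 number ranges at 42 weeks, 1 of the 35 splits of the 7 arrays, the real one, gave as many as 112 probe sets and the highest other gave 2. This argues against a random grouping of single arrays there. However, 1 in 35 is the smallest share these splits can give, and the count was 0 without AJ2, LZ22, LZ23 or LZ25. Run day and number range are the same split.

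Control probe sets for 18S ribosomal RNA, which enter no comparison, read far above the arrays at 24 to 26 weeks on LZ61 to LZ63. The 3' probe set read 21883 on LZ61, 2052 on LZ62 and 8024 on LZ63, against at most 263 at 24 to 26 weeks. The 5' probe set read 31451, 16032 and 10646 on these arrays and 9390 on LZ22, against at most 478.5. The middle probe set read 12521, 237.8 and 324.3, against at most 73.4.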

How the results depend on the processing

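Leaving out LZ22, LZ24 and LZ63 and using the muscle list means as covariates were chosen after seeing the data. Over all alternatives, 51 named genes gave 1267 values, of which 1098 kept direction and side of the threshold, 133 lost the call, 29 gained one and 7 turned direction, and 15 lists gave 434 values, of which 357, 33, 26 and 18 did so. The cause of these changes was not tested. Cyp1a1 passed in all 26 alternative limma fits that kept its probe set. The filter at the 60th percentile removed it. It did not pass the exact permutation test per probe set, whose 792 splits are too few for single probe sets to pass after adjustment. The median log2 difference of all probe sets was -0.04. Noise of MAS5 signals near the background limits dim probe sets.

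The count of 6 probe sets was 17 after quantile normalization, 550 with array weights, 3 with LZ arrays only, 441 with AJ arrays only at 24 to 26 weeks, 14 with LZ22 to LZ25 only at 42 weeks, 12 with LZ61 to LZ63 only, 1 with run day as a random block, 1 without LZ22, LZ24 and LZ63, 10 with muscle covariates and 1 at 1% false discovery. An exact permutation test per probe set, over 792 splits, called 0, with 1031 at an unadjusted p under 0.05 and a smallest adjusted p of 0.162. So few splits cannot pass single probe sets after adjustment, so this 0 does not decide on the 6. Leaving out single arrays gave 4 to 38. The count of 5 lists was 2 after quantile normalization, 3 with medians set equal, 3 without the filter, 8 with array weights, 8 with LZ arrays only, 9 with LZ22 to LZ25 only, 9 without LZ22, LZ24 and LZ63, 8 with muscle covariates and 0 with an estimated correlation, and 3 to 10 without single arrays. With LZ61 to LZ63 only at 42 weeks 5 lists passed, of which 2 were among the main 5, as immunoglobulins, MHC class II and complement were lost. With LZ22 to LZ25 only 3 of the 9 were, as oxidative phosphorylation and complement were lost. With the prefix block 3 of 7 were and with LZ arrays only 3 of 8, as ribosomal proteins and complement were lost. With AJ arrays only 4 of 5 were, as MHC class II was lost.

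The count of 186 probe sets between AJ and LZ arrays was 121 without the filter and 0 to 374 without single arrays. The count of 112 between the number ranges was 292 with medians set equal, 45 without the filter, 23 with eBayes without trend and robust, 0 with array weights and 0 to 84 without single arrays. Where an array left out leaves 1 array in a group, that array is assumed to vary like the others.

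These log2 values turned direction. The ribosomal list was -0.0099 after quantile normalization. Cardiac muscle was 0.082 without the filter, 0.67 with LZ61 to LZ63 only and 0.30 without LZ22, LZ24 and LZ63. Skeletal muscle was -0.14 with array weights, -0.83 with LZ22 to LZ25 only and -0.57 (without LZ63) to 0.55 (without LZ22) without single arrays. Both the prefix block and LZ arrays only gave -0.065 for Sftpc, -0.013 for Rps28, -0.069 for Scgb1a1, -0.017 for alveolar type 2 cells, 0.17 for interferon response and -0.0040 for adipose tissue. T cells were -0.016 with AJ arrays only, -0.11 with LZ61 to LZ63 only and -0.015 (without LZ24) to 0.16 (without LZ63) without single arrays. With LZ22 to LZ25 only Fabp4 was -0.12 and adipose tissue -0.20. MHC class II was -0.018 with LZ61 to LZ63 only.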

Other observations

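Several genes named through lists that did not pass are given here as values at 24 to 26 weeks and 42 weeks, none past 5% false discovery over all probe sets. The proteasome subunit gene Psma4 read 2027 ± 294 (SD, n = 5) and 3206 ± 467 (SD, n = 7) (limma adjusted p = 0.057), while the proteasome list had a median log2 difference of -0.01 over 32 genes (adjusted p = 0.34), 3 of them higher when adjusted over the list alone. The alveolar type 1 cell gene Pdpn read 1379 ± 59.4 and 2014 ± 314 (adjusted p = 0.064), and its list had a median of 0.01 over 9 genes (adjusted p = 0.63), 1 of them higher when adjusted over the list alone. Mdm2, a p53 target, read 863 ± 169 and 569 ± 56.2 (adjusted p = 0.064), and the p53 list had a median of -0.06 over 19 genes (adjusted p = 0.63), 2 of them lower when adjusted over the list alone.

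The hybridisation spike-in controls, bacterial transcripts added in fixed amounts, differed between run days. The BioB 3' control read 850.0 to 1225 on the 3 arrays of day 1 and 170.0 to 240.3 on those of day 4, and the BioC 3' control read 1568 and 2097 on day 2 and 249.6 to 405.5 on day 4. The BioDn 3' control separated the time points, at 7467.8 to 13039.5 at 24 to 26 weeks and 2197.9 to 4368.4 at 42 weeks. The BioB, BioC and CreX 3' controls overlapped between the time points. The ratio of the 3' to the 5' control probe set of beta-actin was 1.24 to 1.28 on day 1 and at most 1.19 on the other arrays, while that of Gapdh was 0.767 to 0.805 on day 1 and 0.766 to 1.04 on the other arrays. The 99th percentile of the signal was 7427 to 7768 on day 1 and 8665 to 9546 on the other arrays. Red blood cell markers had an array median of 1.61 on LZ24 and between -0.32 and 0.34 on the other arrays.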
